A study of Xenopus laevis with 15 samples.

How the data were processed

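The measurement was RNA sequencing of whole Xenopus laevis embryos in 3 groups of 5 libraries: 0.1% ethanol as vehicle, 10 nM NRX204647 and 1 µM NRX204647, with exposure from stage 6 to stage 18. Per the labels' protocols, groups of 25 embryos were exposed in 60-mm dishes holding 10 mL of medium, and each dish was harvested at stage 18 as 5 aliquots of 5 embryos. Total RNA (100 ng) was reverse transcribed and amplified with the NuGEN Ovation V2 system. Libraries were sequenced on an ABI SOLiD 5500xl as single reads of 50 nt without strand information, per the labels' protocols. Reads of overlapping or antisense genes therefore cannot be told apart, and in this species, whose genome holds many paired gene copies from a past duplication, reads shared between near-identical copies could be split between their gene models.

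The authors deposited a single table of FPKM values, fragment counts scaled for gene length and library size, with 45099 gene models and 1 column for each of the 15 libraries. TopHat, Bowtie and Cufflinks are named in the submitters' processing notes. Their versions, the genome build and the annotation are not given in the sources used here. The table has a symbol for 1323 gene models, all within its first 4491 lines. For 709 of them the symbol is not a placeholder, a further 20686 gene models have a dash and 23090 have an empty symbol cell. None of the identifiers was found in the reference table of Xenopus_laevis_v10.1 genes (0 matched), so names came from the deposited table alone.

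Because the unit was FPKM and not counts, tests for read counts were not used for the main results. Values were analysed as log2(FPKM + 1) for the 13192 gene models with a mean of at least 1 FPKM over the 15 libraries (29.3% of the table). Linear models were fitted with limma 3.58.1 in R 4.3.3, with all 3 groups in 1 fit and a mean-variance trend, so that the groups shared an estimate of the spread. Tests were two-sided, and a gene model was called at a Benjamini-Hochberg adjusted p under 0.05. Group levels are the mean ± SD of FPKM over 5 libraries. Library values were compared with exact permutation tests in scipy 1.17.1 under Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

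Sequencing depth was recovered from the values. Within a gene model, FPKM values are multiples of what 1 read is worth, and for 98.8% of the 34147 gene models with a value above 0 in 2 or more libraries every value came out as a whole number of reads within 0.03 reads. This held for 97.4% of the tested gene models (12848). The depth relative to the deepest library and the relative length of each gene model followed from these steps. These whole reads were also tested with limma's voom as an added alternative, which called 2741, 6132 and 3297 gene models at 10 nM against vehicle, 1 µM against vehicle and 1 µM against 10 nM. Totals of recovered reads in tested gene models ran from 2245249 to 9192461 per library. For some gene models, among them rps25, sox2 and mycbp, nearly all recovered values share a common factor. The unit found there may be a fraction of a read, which makes recovered reads and relative lengths too large. Replicates were compared for duplicates. None of the 30 pairs within groups held identical values, and their recovered reads differed by more than sampling noise (chi-square per degree of freedom from 6.04 to 14.9).

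The groups, the tests, the gene lists, most of the other settings and the rule for named genes were set before the data were examined. The rule took, for each dose against vehicle, the 10 largest increases and the 10 largest decreases among called gene models with a symbol whose 5 treated libraries all lay on the same side of the 5 vehicle libraries. For 1 µM against 10 nM it took 5 and 5. It added up to 4 called members of each of 26 gene lists and every measured gene of retinoic acid metabolism and retinoid receptors. Set tests with limma's camera were planned for the lists, but no list had 3 tested members. Shared vehicle libraries were examined with 50 simulations of unchanged groups and with 20 splits of the vehicle libraries between the doses. Neither removes a vehicle dish shared by both doses.

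Also run as set at that time were pseudocounts of 0.1 and 5, no filter, a filter at a mean of 5 FPKM, median-of-ratios scaling, quantile normalization, fits of only the groups compared, library weights, a robust variance prior, the replicate number as a block, stricter thresholds and leaving out each library in turn. Added after the data were seen were scaling to a common total without the most abundant gene model, a correction for gene model length by a lowess curve per library (span 0.3), voom on the recovered reads, thinning of the reads to the shallowest library, and leaving out the libraries with under 0.4 of the deepest library's depth. The fit was tested on simulated data for 1 µM against vehicle with 13192 gene models. It recovered 29.9% of 67 genes changed 1.5-fold, 71.6% of 67 changed 2-fold and 89.4% of 66 changed 4-fold, and 6.62% of its calls were false. The simulation with changed genes gave 136 calls, against 6009 in the data, so its Benjamini-Hochberg cutoff was stricter. These rates therefore do not give the sensitivity for the data. With no changed gene the fit made 0 calls. A simulated length slope over 12848 gene models gave 1186 calls, and 0 after the correction.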

Results

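RNA was sequenced from whole Xenopus laevis embryos that had been kept in 0.1% ethanol (the vehicle), in 10 nM NRX204647 or in 1 µM NRX204647 from developmental stage 6 to stage 18. NRX204647 is a compound known here by its code name. Per the labels, 10 nM was chosen to act selectively on retinoic acid receptor gamma, and 1 µM activates the alpha, beta and gamma receptors. Each group had 5 libraries, each made from 5 embryos, and the 15 libraries were measured as FPKM for 45099 gene models. The protocol in the labels describes dishes of 25 embryos harvested as 5 aliquots, and it gives no further dishes per group. Treatment and dish therefore cannot be separated, and the p-values below measure the spread between aliquots, which leaves out the spread between dishes.

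The deposited table pairs few identifiers with gene symbols. Of the 13192 gene models tested (mean FPKM of at least 1), 314 carried a symbol that was not a placeholder, and these are the ones described by name. The relative sequencing depth, recovered from the steps in the FPKM values, ran from 0.259 of the deepest library (10 nM replicate 2) to 1 (1 µM replicate 2). Its group mean was 0.839 ± 0.189 at 1 µM, 0.455 ± 0.143 at 10 nM and 0.535 ± 0.259 with vehicle (SD, n = 5). Gene models with a mean FPKM from 1 to 2 rested on a median of 25 to 106 recovered reads per library, and some of the genes named below on under 10 in single libraries. The 15 libraries separated by group along the first principal component, which held 39.7% of the variance. Its scores were 31.9 to 39.1 for vehicle, -0.93 to 4.81 for 10 nM and -44.0 to -30.6 for 1 µM. The median correlation between libraries was 0.897 for 10 nM with vehicle, 0.845 for 1 µM with vehicle, and 0.933 or more within each group.

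**Figure D1:**
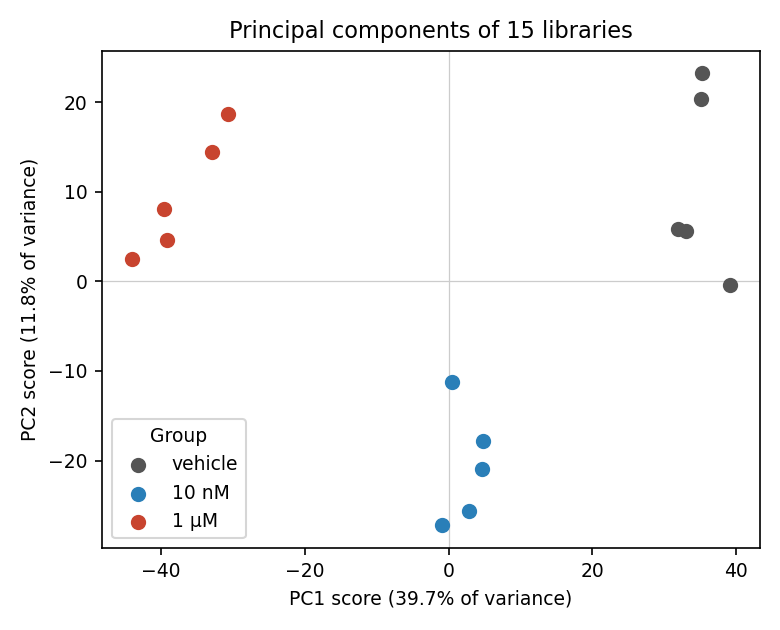
Scores of the 15 libraries on the first principal component (x axis, 39.7% of the variance) and the second (y axis, 11.8%) of log2(FPKM + 1), coloured by group. The 10 nM libraries lie between the vehicle and 1 µM libraries on the x axis, from -0.93 to 4.81.

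In embryos kept in 10 nM NRX204647, transcripts of rdh10, which encodes the retinol dehydrogenase of retinoic acid synthesis, fell from 22.9 ± 3.48 to 14.0 ± 2.13 FPKM (SD, n = 5 each). The largest named decrease was that of sox2, a transcription factor of neural progenitors, from 3.30 ± 0.934 to 0.927 ± 0.822 FPKM. The Myc-family gene mycl fell from 9.90 ± 1.15 to 5.27 ± 0.725 FPKM. The largest named increases were usmg5, a subunit of the mitochondrial ATP synthase, from 5.37 ± 2.64 to 15.1 ± 2.87 FPKM and ntpcr, a nucleoside triphosphatase, which reached 2.53 ± 0.976 FPKM.

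This comparison addresses which genes respond to the gamma-selective dose. By limma with Benjamini-Hochberg adjustment, 3074 of 13192 gene models passed, 1716 higher and 1358 lower at 10 nM, or 1484 and 1613 without vehicle replicate 3. Among the 314 named gene models, 36 were higher, 42 were lower and 236 did not pass. The log2 fold changes, on the log2(FPKM + 1) scale that understates changes of low genes, were -0.67 ± 0.11 for rdh10 (SE, limma adjusted p = 0.000949), -1.24 ± 0.27 for sox2 (adjusted p = 0.00464) and -0.80 ± 0.14 for mycl (adjusted p = 0.00132). They were 1.43 ± 0.26 for usmg5 (limma adjusted p = 0.00182) and 1.02 ± 0.21 for ntpcr (adjusted p = 0.00342). Among called named genes whose 5 libraries at 10 nM all lay on the same side of all 5 vehicle libraries, the 10 largest increases also held cox7a2, a cytochrome c oxidase subunit, from 42.2 ± 10.5 to 84.0 ± 19.1 FPKM, and vdac2, a channel of the outer mitochondrial membrane, from 7.92 ± 1.56 to 12.7 ± 1.33 FPKM. The protein disulfide isomerase gene p4hb rose from 6.36 ± 0.778 to 12.9 ± 2.29 FPKM. Of genes for RNA-binding proteins, hnrnpab rose from 133 ± 31.0 to 227 ± 48.2 FPKM and the mRNA export adaptor gene alyref from 16.9 ± 3.95 to 27.4 ± 3.97 FPKM. The remaining 3 were gadd45gip1, lactb2 and rps25, with log2 fold changes of 0.67, 0.56 and 0.55. The 10 largest decreases with that separation also held sumo3, for a ubiquitin-like modifier, from 339 ± 48.3 to 194 ± 26.9 FPKM, and srsf6, for a splicing factor, from 19.0 ± 2.61 to 11.2 ± 1.28 FPKM. They further held prkci, for an atypical protein kinase C of cell polarity, from 9.13 ± 1.40 to 5.51 ± 0.736 FPKM. The other 4 were cops6-like, mier3, slc44a2 and gigyf1, with log2 fold changes of -0.75, -0.72, -0.62 and -0.59. Other called genes of similar size lacked the separation, among them dpm2 at 0.75 and zcchc24 at -0.96. The sox2 values rested on 0 to 12 recovered reads per 10 nM library and 10 to 31 per vehicle library, and those of ntpcr on 4 to 7 and 1 to 5. Those of usmg5 rested on 15 to 38 recovered reads per 10 nM library and 3 to 25 per vehicle library. Nearly all recovered values of sox2 are even numbers, so its unit may be a fraction of a read and its true read support lower.

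The count fell to 673 when the 5 libraries with under 0.4 of the deepest library's depth were left out, which kept 3 at 10 nM and 2 with vehicle, and 15 of the 20 named genes then missed the threshold (limma adjusted p from 0.0531 to 0.211) with the same sign in 20 of 20. Of the lost calls, the log2 fold change was smaller for usmg5 (1.03 against 1.43), ntpcr (0.77 against 1.02), rdh10 (-0.57 against -0.67), mycl (-0.63 against -0.80), sumo3 (-0.60 against -0.80), mier3 (-0.51 against -0.72) and prkci (-0.39 against -0.64), and close to its value with all libraries for sox2 (-1.25), hnrnpab (0.77) and p4hb (0.87). The adjusted p of gadd45gip1 rose to 0.0574 without 10 nM replicate 1, 0.0567 without replicate 2, 0.0637 without replicate 5 and 0.0666 without vehicle replicate 1 (limma), within a range of 0.0153 to 0.373 over its alternatives.

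At 1 µM, 913 gene models were higher than in vehicle embryos by a log2 fold change of at least 1 and 267 were lower by as much. The gene azin2, for a regulator of polyamine synthesis, rose from 16.3 ± 2.46 to 65.9 ± 11.0 FPKM (SD, n = 5 each). The dynamin gene dnm1, which acts in endocytosis, rose 6.07-fold, from 0.695 ± 0.201 to 4.22 ± 0.289 FPKM. Transcripts of rdh10 fell to 5.36 ± 0.336 from 22.9 ± 3.48 FPKM, the largest named decrease. The next were mycl, from 9.90 ± 1.15 to 2.62 ± 0.774 FPKM, and the zinc finger gene zcchc24, from 11.4 ± 2.56 to 3.73 ± 0.744 FPKM.

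This comparison addresses the response to a dose that, per the labels, activates all of the retinoic acid receptor subtypes. With limma, 6009 of 13192 gene models passed, 3814 higher and 2195 lower, and of the 314 named ones 97 were higher, 51 were lower and 166 did not pass. The log2 fold changes were 1.94 ± 0.16 for azin2 (SE, limma adjusted p = 1.66e-07), 1.63 ± 0.09 for dnm1 (adjusted p = 1.47e-09) and -1.90 ± 0.11 for rdh10 (adjusted p = 3.67e-09). They were -1.61 ± 0.14 for mycl (limma adjusted p = 2.73e-07) and -1.38 ± 0.21 for zcchc24 (adjusted p = 9.44e-05). Other named increases were stard8-like, from 1.27 ± 0.374 to 7.51 ± 1.02 FPKM, and sema3f-like.1, related to a secreted axon guidance protein, from 0.560 ± 0.193 to 3.52 ± 0.804 FPKM. The p4hb level reached 21.9 ± 5.47 FPKM and the usmg5 level 17.4 ± 5.05 FPKM. The aldo-keto reductase gene akr1c2 rose from 1.53 ± 0.653 to 5.93 ± 1.66 FPKM, the mitochondrial adenylate kinase gene ak3 from 0.374 ± 0.294 to 2.71 ± 0.346 FPKM, and dpm2, for a subunit of dolichol-phosphate mannose synthase, from 0.766 ± 0.239 to 3.73 ± 0.553 FPKM. The last of the 10 largest separated increases was mycbp, from 0.811 ± 0.420 to 3.78 ± 0.821 FPKM. In the vehicle libraries ak3 rested on 1 to 5 recovered reads, dpm2 on 2 to 6 and mycbp on 2 to 16. Nearly all recovered values of mycbp are even numbers, so its true read support may be lower. Decreases included zfp36l1, which promotes decay of AU-rich mRNAs, from 11.4 ± 1.09 to 4.35 ± 0.707 FPKM, and the histone-binding gene rbbp4, from 7.75 ± 1.73 to 3.54 ± 0.549 FPKM. The muscle acetylcholine receptor subunit gene chrnd fell from 7.81 ± 1.81 to 3.30 ± 0.705 FPKM and the potassium channel gene kcnj2 from 1.77 ± 0.327 to 0.596 ± 0.0594 FPKM. The tolloid-related gene tll1-like.1 fell from 2.79 ± 0.409 to 1.02 ± 0.115 FPKM. The sumo3 level was 187 ± 35.7 FPKM and that of cops6-like 1.11 ± 0.418 FPKM, against 339 ± 48.3 and 2.91 ± 1.30 FPKM with vehicle. At an adjusted p under 0.05, none of these 20 genes lost its call in the other settings in which it was tested, but kcnj2, cops6-like, sumo3, tll1-like.1 and rbbp4 had log2 fold changes smaller than 1 (-0.79, -0.86, -0.87, -0.91 and -0.93).

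Among the gene models without a symbol, Xelaev18034594m.g rose from 2.29 ± 0.187 FPKM with vehicle to 80.4 ± 8.15 at 1 µM, with a 5.32-fold rise at 10 nM. A second, Xelaev18036884m.g, rose from 3.05 ± 0.906 to 14.1 ± 1.05 and 90.7 ± 6.45 FPKM. The log2 fold changes at 1 µM were 4.63 ± 0.13 and 4.53 ± 0.13 (SE, limma adjusted p = 2.15e-12 and 2.34e-12). Xelaev18047264m.g fell from 47.7 ± 18.2 FPKM to 3.08 ± 2.15 and 0.404 ± 0.208, and Xelaev18044817m.g from 47.1 ± 16.2 FPKM to 5.17 ± 2.70 and 0.755 ± 0.0932. The file does not pair these identifiers with gene names, and no identifier matched the reference table of Xenopus_laevis_v10.1 genes.

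Higher calls made up 63.5% at 1 µM as deposited, and 51.6% with median-of-ratios scaling, 44.7% with quantile normalization, 38.6% after scaling to a common total without the most abundant gene model and 49.7% after a gene length correction. At 10 nM the shares were 55.8% as deposited, and 54.9%, 44.8%, 27.5% and 50.5% in the same order, and 47.9% without vehicle replicate 3.

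**Figure D2:**
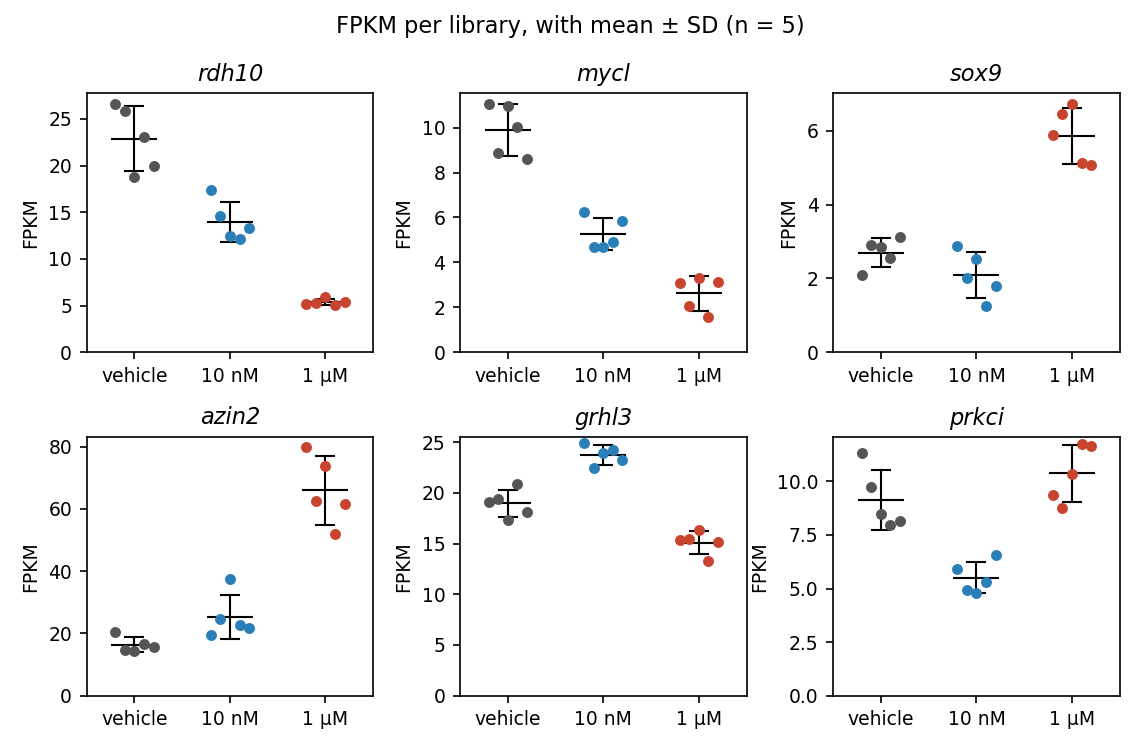
FPKM of 6 named genes (y axis, from 0) in the 5 libraries of each group (x axis), with points for libraries and bars for the mean ± SD. Levels of rdh10 were 22.9, 14.0 and 5.36 FPKM in vehicle, 10 nM and 1 µM embryos, while grhl3 was 18.9, 23.7 and 15.1 FPKM.

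Between the doses, azin2 was higher at 1 µM by a log2 fold change of 1.37 ± 0.16 (SE, limma adjusted p = 1.34e-05) and dnm1 by 1.27 ± 0.09 (adjusted p = 5.36e-08). The neural crest transcription factor gene sox9 stood at 5.86 ± 0.753 FPKM at 1 µM and 2.09 ± 0.631 FPKM at 10 nM (SD, n = 5 each). Levels of rdh10 were lower at 1 µM than at 10 nM by a log2 fold change of -1.23 ± 0.11 (limma adjusted p = 1.01e-06). The muscle receptor gene chrnd was 3.30 ± 0.705 FPKM at 1 µM and 6.87 ± 0.422 FPKM at 10 nM.

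This test asks directly whether a gene differed between the doses, since a call at a single dose does not show a difference. It gave 3136 gene models, 2118 higher and 1018 lower at 1 µM, and for the named ones 57 higher and 21 lower. Among named genes whose libraries at the doses did not overlap, the other increases among the 5 largest were stard8-like, from 2.74 ± 0.737 to 7.51 ± 1.02 FPKM, and sema3f-like.1, by a log2 fold change of 1.09, and the other decreases were mycl, kcnj2 and zfp36l1, at -0.81, -0.75 and -0.69. The mycbp gene, whose libraries overlapped, was also called, by 1.14 ± 0.29 (limma adjusted p = 0.0104). The usmg5 gene, called at both doses, differed between them by 0.17 ± 0.26 (SE, limma adjusted p = 0.692). The prkci level was 10.4 ± 1.32 FPKM at 1 µM, 5.51 ± 0.736 FPKM at 10 nM and 9.13 ± 1.40 FPKM with vehicle, and it was higher at 1 µM than at 10 nM by 0.80 ± 0.11 (limma adjusted p = 7.87e-05). Its difference from vehicle did not pass at 1 µM (limma adjusted p = 0.235). It was 1 of 6 named genes lower at 10 nM, not called at 1 µM against vehicle and higher at 1 µM than at 10 nM. Of those 6, the Wnt co-receptor gene lrp6 and the insulin receptor gene insr, singled out after their values were seen, had log2 fold changes of -0.50 and -0.32 at 10 nM against vehicle, and 0.33 and 0.29 at 1 µM against 10 nM. Over all gene models 122 showed this pattern, and 98 were higher at 10 nM, not called at 1 µM against vehicle and lower at 1 µM than at 10 nM. The shares of higher calls between the doses were 67.5% as deposited, 49.8% with median-of-ratios scaling, 47.6% with quantile normalization, 54.8% with the common total and 51.4% after the length correction.

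Of the gene models called against vehicle, 1432 were higher at both doses, 930 were lower at both and 42 moved in opposite directions. Among the named ones, 34 were higher at both doses and 25 were lower at both, including rdh10, mycl, sumo3 and srsf6. A further 404 of the 1432 were higher at 1 µM than at 10 nM, and 191 of the 930 were lower at 1 µM than at 10 nM. Only 2 named genes moved in opposite directions. The epidermal transcription factor gene grhl3 had a log2 fold change of 0.31 ± 0.08 at 10 nM (SE, limma adjusted p = 0.00900) and -0.31 ± 0.08 at 1 µM (adjusted p = 0.00357). The other, msn-like, singled out after its values were seen, had -0.32 ± 0.10 at 10 nM (limma adjusted p = 0.0341) and 0.50 ± 0.10 at 1 µM (adjusted p = 0.00104). The 10 nM call of grhl3 was lost with quantile normalization (log2 fold change 0.17, limma adjusted p = 0.0818), with the common total (0.15, adjusted p = 0.110) and without the shallow libraries (0.30, adjusted p = 0.162), in a range from 0.00364 to 0.162 over its alternatives.

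Both comparisons used the same vehicle libraries, which raises their overlap. The 2362 gene models called in the same direction at both doses compare with 722 for independent lists (496 higher, 226 lower). With the vehicle libraries split so that the doses shared none, the median overlap was 1242.5, from 728 to 1442 over 20 splits. Each dose then had fewer vehicle libraries, which lowers the number of calls, while 722 comes from the calls with all of them. The fall from 2362 therefore does not measure the effect of sharing alone. In 50 simulations of unchanged groups with shared vehicle libraries, the largest overlap was 0. A fit to unchanged groups makes almost no calls, so this 0 was given in advance and does not measure what sharing adds. The correlation of log2 fold changes across genes, which are not independent replicates, was 0.71 as observed. The median of 50 simulations of unchanged groups, which shared all vehicle libraries as the data did, was 0.50. With split vehicle libraries the correlation was 0.56. The value of 0.50 is no baseline for it, because the doses then shared no vehicle library, and no such simulation was run. The covariance was 0.177 against 0.0210 in the simulations, a difference of 0.156. The vehicle libraries are aliquots that may all come from the same dish. A deviation of that dish would enter both doses even after a split, and the simulations held no such deviation. Neither the split values nor this difference is therefore free of a shared control.

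**Figure D3:**
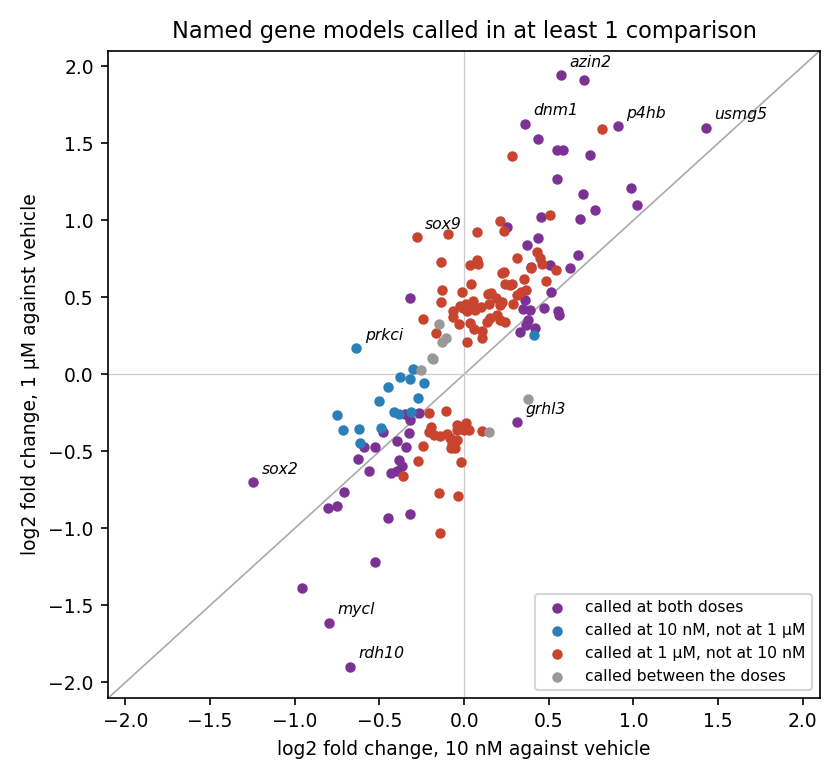
Log2 fold changes at 10 nM (x axis) and 1 µM (y axis) against vehicle for the 173 named gene models called in at least 1 comparison, coloured by the comparison in which they were called, with the line of equal change. The genes rdh10 (-0.67 and -1.90) and azin2 (0.57 and 1.94) lie farther from zero at 1 µM, and grhl3 (0.31 and -0.31) lies in the opposite corner.

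Of the 26 gene lists for retinoid biology, tissues and cell states that were set in advance, 10 had a named tested member, with at most 2 each and 11 genes in all, so no list could be tested as a set. Retinoic acid metabolism was represented by rdh10 alone, lower at both doses. The neural progenitor list held sox2, lower at both doses, with -0.70 ± 0.27 at 1 µM (SE, limma adjusted p = 0.0436), and neural crest held sox9, higher at 1 µM by 0.89 ± 0.13 (adjusted p = 7.06e-05) and not called at 10 nM (adjusted p = 0.143). The hindbrain list held nr2f6, an orphan nuclear receptor gene, higher at 1 µM by 0.59 ± 0.11 (limma adjusted p = 0.000618) and at 2.54 ± 0.463 FPKM at 10 nM against 2.45 ± 0.584 with vehicle. The tailbud list held wnt5b and the notochord list ctgf, higher at 1 µM by 0.45 ± 0.10 and 0.72 ± 0.17 and not called at 10 nM. The preplacodal list held eya1, which at 1 µM had -0.24 ± 0.09 (limma adjusted p = 0.0377), and the epidermis list held grhl3. The cell cycle list held the replication helicase gene mcm7 and the mitotic kinase gene aurkb, lower at 1 µM by log2 fold changes of -0.39 ± 0.12 and -0.36 ± 0.12 and not called at 10 nM. Ribosomal proteins were represented by rps25, higher at 10 nM by 0.55 ± 0.09 and at 1 µM by 0.41 ± 0.09. Its gene model had a recovered relative length of 5.44 (a typical model has about 1), long for a gene of a small protein. Nearly all of its recovered read values share a common factor, however. The unit found may be a fraction of a read, so this length may be too large. In counts adjusted over the list alone, each call above was kept, wnt5b and mcm7 also passed between the doses, and no other call was added. For a list with a single tested member this leaves the p-value unadjusted, so keeping its call was given in advance and adds no support. The other 16 lists had no named tested member. They covered retinoid receptors and corepressors, Hox groups 1 to 4, 5 to 8 and 9 to 13 with Cdx, forebrain and eye, the midbrain-hindbrain boundary, and cement and hatching glands. They also covered presomitic mesoderm, skeletal muscle, heart, pronephros, primary neurons, endoderm, blood and vessel, stress and apoptosis, and signalling components of the BMP, Wnt, FGF and Notch pathways.

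The 1 µM calls of sox2, eya1 and aurkb lay near the threshold. Without the single libraries whose absence ended them, the log2 fold changes were -0.56 to -0.73 for sox2, -0.21 to -0.24 for eya1 and -0.28 to -0.33 for aurkb, against -0.70, -0.24 and -0.36 with all libraries. The limma adjusted p of sox2 reached 0.116 without 1 µM replicate 1 and 0.103 without vehicle replicate 1, and it was over 0.05 without 1 µM replicates 2, 3 and 5, vehicle replicates 2, 3 and 5 and 10 nM replicate 2. With all libraries it was 0.210 with a pseudocount of 0.1, 0.0855 with no filter, 0.0556 with library weights, 0.0501 with a replicate block and 0.0512 with voom. That of eya1 reached 0.0938 without 1 µM replicate 1 and was also over 0.05 without 1 µM replicates 4 and 5 and vehicle replicates 1, 2, 4 and 5. That of aurkb reached 0.0661 without 1 µM replicate 2 and was over 0.05 without replicates 1 and 3. Over all alternatives these p-values ranged from 0.00642 to 0.301 for sox2, 0.000716 to 0.107 for eya1 and 0.00345 to 0.113 for aurkb. The 1 µM call of mcm7 was lost without the shallow libraries (-0.29, limma adjusted p = 0.231, in a range from 0.000848 to 0.231). That of rps25 was lost with quantile normalization (0.22, adjusted p = 0.0673), with the common total (0.18, adjusted p = 0.115) and without the shallow libraries (0.32, adjusted p = 0.0779), in a range from 0.000664 to 0.115, and its 10 nM call without the shallow libraries (0.43, adjusted p = 0.0977, in a range from 0.000243 to 0.0977).

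Fold changes also moved with the relative length of the gene model, as recovered from the FPKM value of a single read. Where the unit found was a fraction of a read, this length is too large. The recovered values of wnt5b and tll1-like.1, with relative lengths of 9.13 and 19.0, mostly share a common factor. The longest gene models may therefore hold such cases, and the trend is not settled as one of length alone. Of the 1606 shortest gene models, an eighth of those with a recovered length, 295 were higher and 60 were lower at 10 nM, against 84 and 246 of the 1606 longest. At 1 µM these numbers were 478 and 101 for the shortest and 369 and 335 for the longest. Spearman's correlation across gene models, which are not independent replicates, was -0.220 at 10 nM and -0.174 at 1 µM against vehicle, and -0.0216 between the doses. Named genes with short models moved both ways. Among the increases were usmg5 and ntpcr, with relative lengths of 0.0577 and 0.0730. After the length correction their log2 fold changes at 10 nM were 1.15 (limma adjusted p = 0.00353) and 0.75 (adjusted p = 0.0172), in ranges of p from 0.000756 to 0.0644 and 0.00172 to 0.173 over all alternatives. Among the decreases, sumo3 had the shortest model, with a relative length of 0.00615 and 17 to 105 recovered reads per library, and after the correction its log2 fold change was -1.10 at 10 nM and -1.64 at 1 µM, against -0.80 and -0.87 before. Those of zcchc24 (0.0685) at 1 µM and of sox2 (0.163) at 10 nM were -1.79 and -1.49, against -1.38 and -1.24. The named increase gadd45gip1, with a relative length of 0.160, lost its call after the correction at 10 nM (0.43, limma adjusted p = 0.139) and at 1 µM (0.44, adjusted p = 0.0883, in a range from 0.00225 to 0.0888), and lactb2 lost its call at 1 µM (0.13, adjusted p = 0.397, in a range from 0.00575 to 0.397). The 10 nM calls of azin2, akr1c2 and ak3 were lost as well, with log2 fold changes of 0.43, 0.45 and 0.37 after the correction against 0.57, 0.58 and 0.55 before it (limma adjusted p = 0.0606, 0.0526 and 0.136), in ranges from 0.0119 to 0.221, 0.00330 to 0.0932 and 0.0148 to 0.136. Without the shallow libraries these 10 nM calls were lost too (limma adjusted p = 0.221, 0.0932 and 0.0764). So were the 1 µM calls of gadd45gip1 (limma adjusted p = 0.0846) and lactb2 (0.0531). The ak3 call was also lost with no filter (limma adjusted p = 0.0793) and without 10 nM replicate 1 (0.0814). These losses are therefore not particular to the length correction. The slope of log2 values on log2 length ran from 0.0123 to 0.0410 in the vehicle libraries, -0.0196 to 0.00183 at 10 nM and -0.0269 to -0.00453 at 1 µM. Each dose differed from vehicle with p = 0.00794 in a two-sided exact permutation test, the smallest p that 5 against 5 libraries can give, and 0.0119 after Benjamini-Hochberg adjustment over 3 comparisons.

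**Figure D4:**
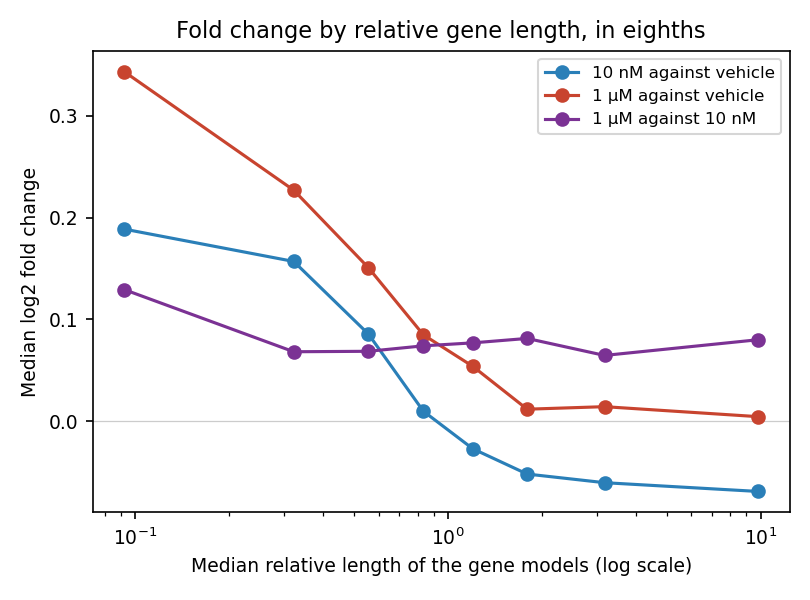
Median log2 fold change (y axis) in eighths of the gene models ordered by relative length (x axis, log scale), for each comparison. The median at 10 nM against vehicle falls from 0.19 in the shortest eighth to -0.07 in the longest, and at 1 µM against vehicle from 0.34 to 0.00.

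The most abundant gene model, which had no symbol, took a share of the FPKM total that ran from 14.5% to 45.5% across libraries. Its mean share was 20.5% ± 5.06 at 1 µM, 24.5% ± 6.00 at 10 nM and 32.3% ± 8.07 with vehicle (SD, n = 5). The difference between 1 µM and vehicle had p = 0.0238 in a two-sided exact permutation test and 0.0571 after Benjamini-Hochberg adjustment over the library comparisons.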

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

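No test in this part was chosen after its result was seen. Within each group of 5 libraries, the highest or lowest library stood apart where its gap to the nearest other library exceeded 0.71 of the group's range (Dixon's test). This was applied to 153 groups of values, of which 9 were picked out, against 7.65 expected for normally distributed values in unselected groups. Many of the groups were FPKM values of genes picked from these data, some with few reads. The expected number therefore does not tell whether libraries were outlying.

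The total FPKM of 1 µM replicate 5 was 165456, against at most 158606 in the other libraries of its group. Levels of sumo3 reached 423 FPKM in vehicle replicate 1, where the other vehicle libraries had at most 336. The cops6-like gene stood at 5.19 FPKM in vehicle replicate 2, against at most 2.63. The akr1c2 gene stood at 2.67 FPKM in vehicle replicate 2, against at most 1.41. The ntpcr gene stood at 1.28 FPKM in vehicle replicate 4, against at most 0.657. The gadd45gip1 gene was at 0.789 FPKM in vehicle replicate 1, where the others ran up to 1.76. Levels of azin2 reached 37.4 FPKM in 10 nM replicate 3, against at most 24.5. The rps25 gene was at 14.0 FPKM in 10 nM replicate 4, where the others had at least 17.2. Levels of nr2f6 reached 4.66 FPKM in 1 µM replicate 4, against at most 4.10. No biological explanation was tested for these values.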

How the results depend on the processing

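Tests chosen after the data were seen are those with the common total, length correction, voom, thinned reads and without shallow libraries. The directions of all 46 gene models named by the rule or by identifier were kept wherever a called value was recomputed. Leaving out each library in turn gave 2506 to 3097 calls at 10 nM, 5375 to 6031 at 1 µM, 2572 to 3299 between the doses and an overlap of 1999 to 2342. Among these fits, higher calls outnumbered lower ones at 10 nM except without vehicle replicate 3, which gave 1484 higher and 1613 lower (47.9% higher). With all libraries, lower calls also outnumbered higher ones at 10 nM with quantile normalization (44.8% higher) and with the common total (27.5% higher).

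With a filter at a mean of 5 FPKM, which tests fewer gene models, calls were 1560 at 10 nM (1018 higher, 542 lower), 2250 at 1 µM (1493 and 757) and 1047 between the doses (649 and 398), and the overlap was 1237. With an absolute log2 fold change of at least 1 they were 292 (225 and 67), 1180 (913 and 267) and 461 (357 and 104). At an adjusted p under 0.01 they were 1333 at 10 nM (810 and 523), 1444 lower at 1 µM, and 1886 between the doses (1297 and 589). Without the shallow libraries, which leaves fewer samples, 673 were called at 10 nM (477 and 196), 607 of them also called with all libraries, and the overlap was 609. Lower calls rose to 3514 at 1 µM and 1721 between the doses with quantile normalization, to 1614 between the doses with median-of-ratios scaling, and to 3118 at 10 nM and 4072 at 1 µM with the common total. These scalings moved the median log2 fold change of all gene models at 1 µM by -0.13 (quantile) and -0.18 (common total), and the length correction by -0.11.

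With the replicate number as a block (replicate block), calls were 2933, 5966 and 3051. Same-numbered libraries did not deviate together (r from -0.110 to 0.114, over 0.1 in 1 of 15 pairs), and 4 of 15 libraries correlated best with their own number, so the numbers give no pairing. Set tests of the gene lists were not run because no list had 3 tested members, and alternatives planned for read counts were not run on FPKM. The simulated 1.5-fold changes were recovered at 29.9%, with far fewer changed gene models and so a stricter cutoff than in the data. This rate does not give the sensitivity for the data. Missing the threshold still does not show that a gene model was unchanged.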

Other observations

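The tests of gene groups in this part, the scaling without the most abundant gene model and the length correction were chosen after the values were seen. The symbols allowed 7 functional groups to be formed by hand, and limma's camera compared each with all other tested gene models. Members were chosen with the values known, so the camera p-values are descriptive and give no independent support. Of 17 chromatin regulators, 7 were lower and none was higher at 10 nM, and 9 were lower and none was higher at 1 µM (camera adjusted p = 0.00465 and 0.00112). Those calls were lost with an estimated correlation (adjusted p = 0.148 and 0.0750). The transcriptional cofactor gene hcfc1 fell from 13.6 ± 0.981 to 9.17 FPKM at 10 nM and 9.55 ± 1.27 at 1 µM, and the remodeller gene ino80 from 3.12 ± 0.493 to 1.97 ± 0.445 and 2.18 ± 0.389 (SD, n = 5). The remodeller gene smarca5 was at 17.4 ± 1.55 FPKM with vehicle, 17.1 ± 0.934 at 10 nM and 11.4 ± 1.18 at 1 µM. Between the doses 4 of the 17 were lower (adjusted p = 0.157), although their median log2 fold change was 0.05. After the length correction 8 were lower at 10 nM and 12 at 1 µM (adjusted p = 0.0185 and 0.00322).

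Of 5 genes of muscle and the neuromuscular junction, none was called at 10 nM (camera adjusted p = 0.728, or 0.782 with an estimated correlation), 3 were lower at 1 µM (adjusted p = 0.00423, or 0.0750 with an estimated correlation) and 4 were lower at 1 µM than at 10 nM (adjusted p = 0.000159, or 0.0330 with an estimated correlation). The members chrnd and kcnj2 had already been named among the largest decreases at 1 µM against vehicle and between the doses. The low p-values of this group therefore follow in part from that choice. Besides chrnd and kcnj2, the Z-disc gene ldb3-like.1 fell from 2.46 ± 0.309 to 1.04 ± 0.303 FPKM at 1 µM. The receptor subunit gene chrng was at 8.54 ± 1.29 FPKM at 10 nM and 5.63 ± 1.32 FPKM at 1 µM. Of 19 genes for mitochondrial proteins, 7 were higher at 10 nM and 8 at 1 µM (camera adjusted p = 0.0278 and 0.0653), and the first call was lost with an estimated correlation (adjusted p = 0.176) and after the length correction (0.185). The secretory pathway group of 18 had 9 genes higher at 1 µM (camera adjusted p = 0.0648) and 5 higher at 1 µM than at 10 nM (adjusted p = 0.0328, or 0.336 with an estimated correlation), among them p4hb and ctage5, from 2.23 ± 0.191 to 4.81 ± 0.510 FPKM. At 10 nM, 4 of this group were higher and 1 was lower (camera adjusted p = 0.589). The groups for pre-mRNA processing, cell division, and ubiquitin, SUMO and the proteasome did not pass in any comparison (camera adjusted p from 0.157 to 0.908).

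The calls at 1 µM were 63.5% higher, and this excess was examined further. Deeper sequencing of the 1 µM libraries is argued against, because the share stayed at 63.5% (63.5146 before rounding) when all libraries were thinned to the depth of the shallowest. Scaling without the most abundant gene model gave 38.6% higher and the length correction 49.7%, but these settings also moved the median log2 fold change of all gene models by -0.18 and -0.11, which lowers the share whatever the cause. Neither value therefore decides, and median-of-ratios scaling, which leaves the length trend in place, also gave 51.6%. The share of the most abundant gene model, the length trend and a broad response to the compound all stay open.

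Gene models of short recovered length were higher relative to those of long recovered length in the treated libraries. That length is too large where the unit found was a fraction of a read, so the trend is not settled as one of length alone. Few reads behind short gene models are argued against, because Spearman's correlation at 10 nM was -0.227 among the 7472 gene models with a mean of at least 100 recovered reads over the 15 libraries. Single libraries, above all the shallow ones, can hold fewer. Library quality that varies from library to library within groups is argued against too, since 0 of the 10 treated libraries had a length slope within the range of the vehicle libraries. RNA quality or amplification that differed between whole dishes and an effect of the compound stay open, because dish and treatment cannot be separated in this design. A response that favours short transcripts remains a hypothesis that was not tested, and the value of 0 does not decide it.

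Chance assignment of libraries to groups is argued against for each count of calls. Of 100 splits of the 10 libraries, the real split included, 1 gave as many calls as the real one in each comparison. The real counts were 3074 at 10 nM, 6009 at 1 µM and 3136 between the doses, and the highest among the other splits were 209, 2 and 2. Splits that mix separated groups widen the spread within them, so these low counts do not give a rate of false calls. The libraries are aliquots, so the splits do not address a difference between dishes.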
